A study of Mus musculus with 6 samples.

How the data were processed

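RNA was measured in 6 heart libraries of C57BL/6 mice aged 16 weeks, 3 from wild-type animals and 3 from animals that lack the urea transporter UT-B, the product of Slc14a1. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit. The title, source and tissue labels say heart, whereas the design text and the extraction protocol speak of retina, so the levels of cardiac and retinal marker genes were examined in every library. Nothing in the labels says that each library came from a separate animal, so p-values measure the spread between these libraries, which may in part be technical.

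Tables of 3 kinds of RNA were used. The mRNA table holds whole-number read counts per gene for 21878 genes, as deposited by the authors, with a companion table of FPKM values by the authors. The lncRNA table holds expected counts per transcript for 131778 transcripts, as deposited by the authors, which are estimates that need not be whole because reads shared by overlapping isoforms are divided among them; a companion table gives deposited FPKM values. The circRNA table holds deposited counts of reads across back-splice junctions for 6139 circular RNAs, in which a value is 0 or at least 2 in each library, and a companion table gives deposited RPM values. The ratio of junction counts to RPM was constant within a library, so each library was scaled by a single total. The aligner, counter and annotation behind each table are not given in the sources used here; the submitters' processing notes name Bowtie 0.12.2 and the build mm9 with no role. Whether counting used strand is not given either, so reads of overlapping sense and antisense genes could not be told apart. The header line of each table had lost separators between its sample names, and the names were read in the order in which the header writes them.

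The coordinates in the lncRNA table were checked against the GRCm38.p6 RefSeq annotation: 98.2% of 32669 lncRNAs described there as nested in a gene lay within the GRCm38 span of that gene, against 33.0% after a shift of the coordinates by 100 kb. Coordinates of lncRNAs are therefore given as the table gives them, with GRCm38 as the build they matched; those of circRNAs are given as their table gives them, with no such check. The mRNA table gives no positions. The plan had been to take gene positions from the tables, so neighbouring genes were instead found from the RefSeq annotation of GRCm38.p6 through the gene identifiers, a source chosen after the data had been seen; 99.7% of the tested genes had a position, and no coordinates from it are printed.

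Total counts per library were 38809619 to 45011327 for mRNA, 4922799 to 6650457 for lncRNA and 15776 to 18269 junction reads for circRNA. Each table was tested on its own with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest) with genotype as the term. Expected counts were rounded to whole numbers for the tests. Features were kept by filterByExpr, with a minimum count of 10 and a minimum total of 15, which left 13831 genes, 10169 lncRNA transcripts and 282 circRNAs; the circRNA library size was the total of all junction reads. TMM factors were computed per table, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Levels are TMM-normalised CPM (counts scaled to library size) with the SD over 3 libraries. The standard error of a log2 fold change was derived from the fold change and the F statistic. A difference for 1 transcript that is not in the filtered table was tested by an exact two-sided permutation test of log2(CPM + 0.1), where 3 against 3 libraries cannot go below p = 0.1. Where all libraries of a group had 0 reads, the fold was bounded by taking 3 counts over the whole group as the floor. Intervals and floors cover counting error or the fit only.

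Before the data were examined, 35 gene lists, the rule for named genes and the alternatives were fixed. The lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01 where at least 5 members passed the filter, with adjustment over the 31 lists tested; camera with an estimated correlation and fry were alternatives. Named mRNAs were the 12 with the largest rise and the 12 with the largest fall among genes with adjusted p under 0.05, mean log2 CPM of at least 1 and no overlap between the groups; where fewer passed, the places were filled by the smallest unadjusted p under the same level and overlap conditions. Slc14a1 and Gata5 were always named, as were for each list up to 4 members past the threshold or else the 2 with the smallest p. For lncRNA 5 in each direction and NONMMUT140591.1 were named by the same rule, and for circRNA 5 in each direction with no condition on level. Some genes that the rule names are not reported here. All other named features were chosen after their values were seen, among them Myl4, Sln, Hspa1a, Gja5 and the other genes given as markers of a tissue or a library, and those named because a setting called few. A planned comparison of circRNAs with their host genes was not made, because the circRNA table names no host.

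The alternatives were DESeq2 1.42.0 with its own size factors and default independent filtering (restored to the default after a first run with another alpha had been seen), RLE factors, library totals alone, no filter or a filter at CPM above 1 in 3 libraries, the replicate number as a block, limma on log2 of the deposited FPKM or RPM with a pseudocount of 1 or 0.1, other library sizes, leaving out each library, and an unadjusted threshold with at least a 2-fold change. A term for the presence of Y-linked reads, sums of lncRNA counts over overlapping transcripts of 1 strand, and an unadjusted threshold for genes beside Slc14a1 were added after the data had been seen.

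The tests were tested on simulated data: negative binomial counts were drawn from the real means, dispersions and library sizes, with 200 features changed. For the mRNA comparison, edgeR called 30% of the genes changed 1.5-fold, 72% at 2-fold, 90% at 4-fold and 100% at 8-fold among 13836 genes, with 7 false calls, and made 0 calls when no gene was changed. DESeq2 called 42%, 78%, 92% and 98% at these folds among 14256 genes, with 36 false calls, and 7 calls when no gene was changed. For the lncRNA comparison, edgeR called 0% of transcripts changed 1.5-fold, 2-fold or 4-fold and 4.08% of those changed 8-fold among 10315 transcripts. DESeq2 called 0%, 2.22%, 37.0% and 81.6% of lncRNAs at these folds among 9795 transcripts, with 40 false calls, and 13 calls when none was changed. For the circRNA comparison, edgeR called 0% at 1.5-fold, 28.6% at 2-fold, 88.9% at 4-fold and 100% at 8-fold among 301 circRNAs. In simulated mRNA counts camera called 3 of 3 lists raised 1.5-fold and 0 others, and 1 list when none was raised. In all of these simulations each feature was drawn independently, so differences between libraries that many genes share were absent. The shares called may therefore not carry over to the real tables. In the real counts Myo3a, with 109 to 111 reads in wild type and 0 in knockout, had an edgeR adjusted p of 0.0856. The 0 mRNA calls thus do not exclude large changes. For the lists, the real correlation between genes of a list was absent. The few false calls of camera in these counts therefore do not carry over to the real lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.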

Results

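The series compared hearts of wild-type mice with hearts of mice lacking UT-B, a membrane protein that lets urea cross the cell membrane. Its title sets the work in conduction block of the knockout heart and proposes a role of the long noncoding RNA NONMMUT140591.1 in the regulation of Gata5, which encodes a zinc-finger transcription factor of heart development. Protein-coding genes, lncRNAs and circular RNAs were counted in 3 wild-type and 3 knockout libraries. Total mRNA counts ran from 38809619 in wild-type replicate 1 to 45011327 in knockout replicate 3, the lncRNA counts from 4922799 to 6650457, and the junction reads of circRNAs from 15776 to 18269. The lncRNA counts were concentrated in few transcripts, the 20 most abundant taking 76.6% to 83.7% of each library. Every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of at least 17.4 for mRNA, 15.1 for lncRNA and 2.91 for circRNA, so no library was a copy of another.

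All 6 libraries were dominated by genes of heart muscle. Myh6, the main myosin heavy chain of the adult mouse heart, stood at 42631 to 46880.6 CPM and Ttn, the giant sarcomeric protein titin, at 30828 to 41649 CPM. The 20 retinal marker genes summed to 25.7 to 34.9 CPM per library, and the highest single value among them was 34.3 CPM for Rom1. Only 3 of the 20 passed the filter, and of these Pde6g and Sag had the smallest p (edgeR adjusted p = 0.829 and 0.897). None of the 12 thymus, lung and airway markers passed the filter, and the 26 mitochondrially encoded names were matched by 0 genes of the table.

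The libraries differed in ways the genotype labels do not give. Reads of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 14697 in wild-type replicate 2, 14385 in wild-type replicate 3 and 15379 in knockout replicate 1, and to 5 to 10 in the other 3 libraries, so that both genotypes held both kinds. The 3 libraries with Y-linked reads also held more of the atrial muscle transcripts: Myl4, an atrial myosin light chain, stood at 644, 415 and 308 CPM in them and at 55.9 to 66.8 CPM in the others. Sln, which encodes the atrial calcium pump regulator sarcolipin, stood at 177, 114 and 82.3 CPM against 11.8 to 16.2. The first principal component of the mRNA table held 30.9% of the variance and parted these 3 libraries from the other 3. Knockout replicate 1 also had 556 CPM of the heat shock gene Hspa1a, against 4.14 to 25.4 CPM in the other 5 libraries.

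The targeted gene, Slc14a1, was barely detected in either group. Wild-type libraries held 6, 17 and 17 reads and knockout libraries 9, 25 and 14, in replicate order. Mean levels were 0.318 ± 0.141 CPM in wild type and 0.365 ± 0.180 CPM in knockout (SD, n = 3 each), a log2 fold change of 0.19 with a standard error of 0.57 (edgeR adjusted p = 0.954). The 95% interval of the log2 fold change, -1.40 to 1.79, is wide. It was computed on the residual degrees of freedom alone, fewer than the edgeR test had, so it is wider than that fit gives. Reads over undeleted parts of a targeted gene still count toward that gene. The gene therefore did not check the genotype labels, and genotypes below are those the labels give.

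Gata5 and NONMMUT140591.1 varied more within each genotype than between the genotypes. Gata5 stood at 1.28 ± 1.14 CPM in knockout and 1.21 ± 0.463 CPM in wild type (SD, n = 3 each), a log2 fold change of 0.08 with a standard error of 0.62 (edgeR adjusted p = 0.985). Its reads numbered 35, 43 and 72 in wild-type replicates and 104, 24 and 33 in knockout replicates, and without knockout replicate 1 the Gata5 level had a log2 fold change of -0.94 (edgeR adjusted p = 0.625). NONMMUT140591.1 lies on chromosome 11 from 86849809 to 86871051 on the plus strand, in an intergenic region 15577 bp upstream of LOC108167918 on the same strand. Its estimated reads were 0.0025, 5.98 and 13.4 in wild-type replicates and 28.5, 0.326 and 0.212 in knockout replicates, too few to pass the filter. The means were 1.86 ± 3.15 CPM in knockout and 1.25 ± 1.33 CPM in wild type (SD, n = 3), and an exact two-sided permutation test gave p = 1, the smallest possible being 0.1. Both RNAs were highest in the 3 libraries with Y-linked reads: the lowest of these held 0.975 CPM of Gata5 and 1.10 CPM of NONMMUT140591.1, against highest values of 0.909 and 0.0586 CPM in the other 3. For Gata5 these 2 values come from 43 and 35 reads, a gap that counting error alone could give. The CPM of Gata5 is scaled to the mRNA counts and that of NONMMUT140591.1 to the far fewer lncRNA counts. The CPM values of the 2 RNAs therefore do not compare their abundance. No miRNA was measured here.

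**Figure D1:**
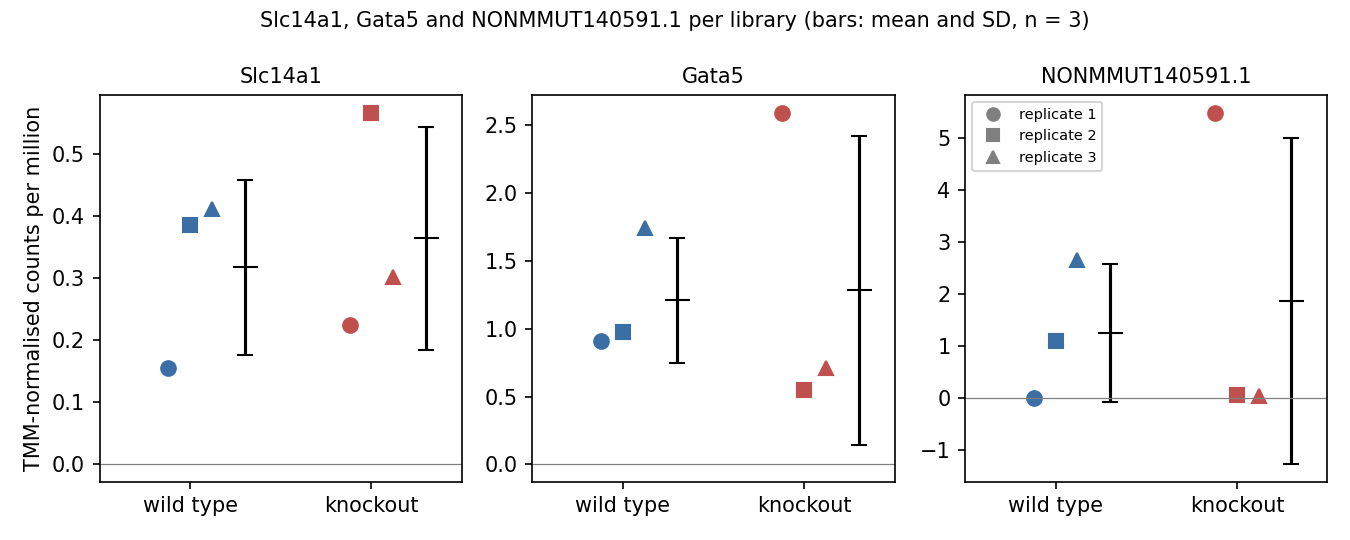
TMM-normalised CPM of Slc14a1, Gata5 and NONMMUT140591.1 in each library, by genotype, with a marker per replicate and bars for the mean and SD of 3 libraries. Knockout replicate 1 has the highest Gata5 level (2.59 CPM) and the highest NONMMUT140591.1 level (5.49 CPM), and the groups overlap in every panel.

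In the whole mRNA table, the genes with the smallest edgeR p between genotypes were Myo3a, an unconventional myosin of sensory cells, and Cngb3, a cyclic nucleotide-gated channel subunit, both lower in knockout. Myo3a, named after its values were seen because its level lies under that of the naming rule, had 111, 109 and 110 reads in the wild-type replicates and 0 in each knockout replicate. Knockout was thus at least 116-fold lower, with 3 counts over the group as the floor (edgeR adjusted p = 0.0856). Cngb3 stood at 2.77 ± 0.337 CPM in knockout and 10.04 ± 1.93 CPM in wild type, 3.62-fold lower (edgeR adjusted p = 0.0908). edgeR called 0 of 13831 genes, and DESeq2 called 77 (34 higher, 43 lower). With edgeR 922 had an unadjusted p under 0.05 (429 higher and 493 lower in knockout), where 691.6 were expected by chance. Other splits of the libraries, 3 against 3, gave 1168 where the split followed the Y-linked reads, the Y-linked genes included, and 360 to 716 elsewhere. The excess alone therefore does not mark an effect of genotype. The groups did not overlap for 1801 genes, 13.02% of those tested, where chance gives 10%. Leaving out knockout replicate 3 gave 1 call, the macrophage receptor Cd163, and no other library left out gave any.

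Of the 12 genes of the naming rule that were higher in knockout, 0 passed the threshold with edgeR and all 12 with DESeq2, where the largest adjusted p was 0.0126 for Fam213b. The rule picked the named genes of either direction by edgeR p from the same counts, so their DESeq2 calls are not separate evidence. Myot, which encodes the Z-disc protein myotilin, stood at 108 ± 18.4 CPM in knockout and 49.5 ± 6.54 CPM in wild type, a log2 fold change of 1.13 with a standard error of 0.14 (edgeR adjusted p = 0.106). Bdh1, the mitochondrial enzyme that interconverts the ketone bodies acetoacetate and 3-hydroxybutyrate, was 1.94-fold higher at 283 ± 45.3 against 146 ± 16.1 CPM (edgeR adjusted p = 0.123). Gabbr1, a GABA-B receptor subunit, was 2.54-fold higher and Edn3, which encodes endothelin 3, 2.49-fold higher, from 5.12 and 2.85 CPM in wild type. Nqo1, an NAD(P)H quinone dehydrogenase of the oxidative stress response, stood at 75.1 ± 3.88 against 50.7 ± 5.96 CPM (edgeR adjusted p = 0.269). The others were Mn1, 2210407C18Rik, Clic5, Prune2, Rttn, Phka1 and Fam213b, with log2 fold changes from 0.36 for Phka1 to 1.36 for 2210407C18Rik. With the presence of Y-linked reads as a term, Myot passed the threshold (edgeR adjusted p = 0.0114).

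Of the 12 named genes that were lower in knockout, 0 passed with edgeR and all 12 with DESeq2, where the largest adjusted p was 0.00407 for Enpp5. Kcnd2, the channel subunit behind the transient outward potassium current of the ventricle, stood at 47.3 ± 2.83 CPM in knockout and 64.0 ± 1.78 CPM in wild type, a log2 fold change of -0.44 with a standard error of 0.07 (edgeR adjusted p = 0.227). Slc9a3, a sodium/hydrogen exchanger, was 5.26-fold lower and Gpr158, an orphan G protein-coupled receptor, 5.75-fold lower, at mean levels of 3.45 and 6.20 CPM in wild type. Itgb6, an integrin subunit, stood at 44.0 ± 7.03 against 69.4 ± 2.13 CPM, and Iigp1, an interferon-inducible GTPase, at 120 ± 3.84 against 213 ± 48.3 CPM. Eif3j2, a near copy of another translation factor gene whose reads the counting could have split, had a log2 fold change of -1.35. The others were Rbfa, Pqlc1, Scin, Enpp5 and Zc3h6, with log2 fold changes from -0.47 for Enpp5 to -0.88 for Scin.

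**Figure D2:**
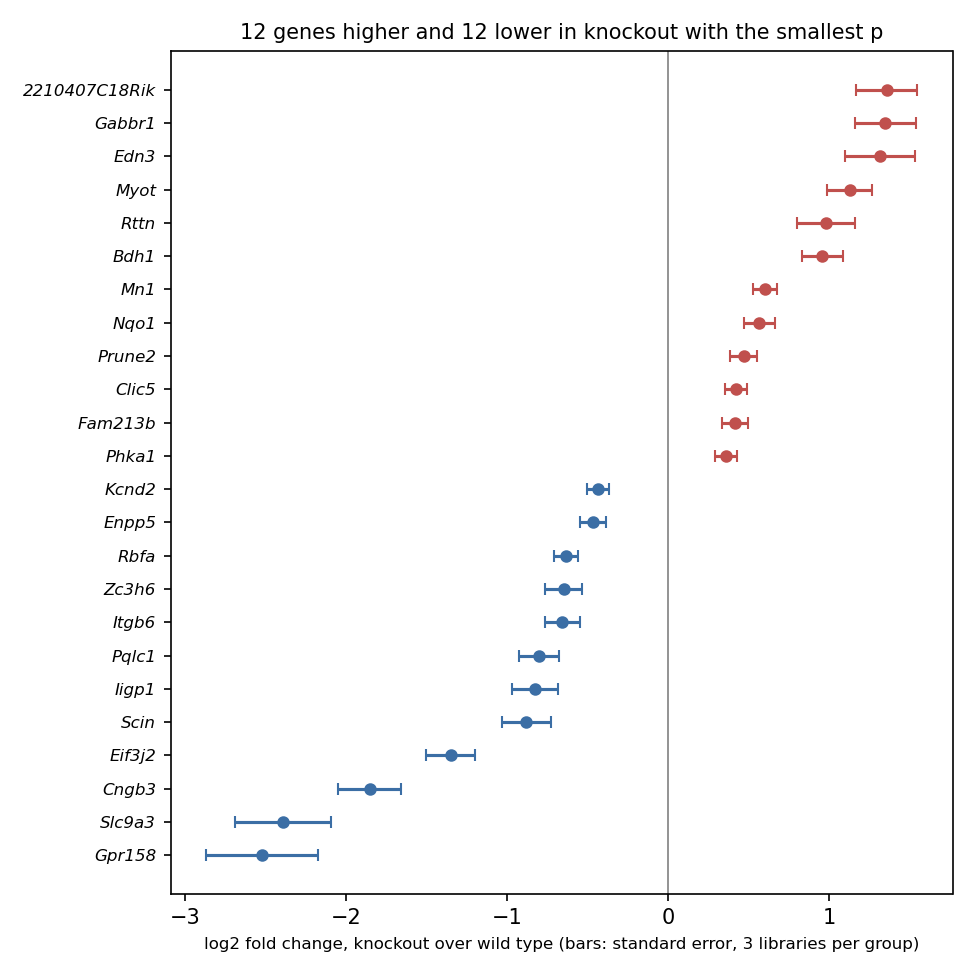
Log2 fold change of knockout over wild type for the 24 named genes, with bars for the standard error of the edgeR fit on 3 libraries per group. Values run from -2.52 for Gpr158 to 1.36 for 2210407C18Rik, and 0 of the 24 genes passed the adjusted threshold with edgeR and all 24 with DESeq2. The genes were picked by their edgeR p from the same counts.

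Of the 35 gene lists, 31 had enough measured members to test, and no member of any list passed the edgeR threshold over all genes. DESeq2 called members that include Kcnd2, Nqo1, Myom2, Bgn and Tubb3. camera called 10 lists, 4 toward higher and 6 toward lower levels in knockout, and 0 of them held with an estimated correlation, where the smallest adjusted p was 0.754, or with fry, where it was 0.822. Among the called lists the estimated correlation ran from 0.0115 for the conduction genes to 0.707 for the oxidative phosphorylation genes, against the preset 0.01. Correlation was not the only difference: the conduction genes went from an unadjusted camera p of 0.00578 to 0.0537 at nearly the same correlation. The variant with an estimated correlation rests on the residual degrees of freedom, which leave few calls within reach. Its 0 calls therefore do not tell whether correlation between genes made the 10. fry's test for changes in either direction gave 3 lists, the ventricular markers (adjusted p = 0.00365), the urea and aquaporin genes (0.0306) and the Schwann and neuronal markers (0.0306). Adjusted over the list alone, 1 member passed in the list of conduction and ion channel genes and in that of ventricular markers (Kcnd2), 1 in the oxidative stress list (Nqo1) and 1 in the list of Schwann and neuronal markers (Tubb3). Tubb3, a neuronal tubulin, had a log2 fold change of 3.12 from a wild-type level of 0.131 CPM.

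Genes of cardiac conduction and ion channels were lower as a set: 22 of 36 measured members were lower in knockout, with a median log2 fold change of -0.07 (camera adjusted p = 0.0179; adjusted p = 0.754 with an estimated correlation). Kcnd2, with a log2 fold change of -0.44 (edgeR adjusted p = 0.227), had the smallest p. The call was lost without wild-type replicate 3 (camera adjusted p = 0.103), knockout replicate 1 (0.0618) or knockout replicate 2 (0.0885). It held with Y-linked reads as a term (0.00583), a setting in which edgeR called 2 genes, Myot as higher and Scn4b of this list as lower. The list's score, the mean log2 CPM of its members against the mean of all libraries, was 0.036 to 0.127 in wild type and -0.150 to -0.021 in knockout. The atrial markers were lower in knockout as well (12 of 13 members, median log2 fold change -0.96). Gja5, a connexin of the conduction system named after its values were seen, ranged from 12.2 to 21.2 CPM over the 6 libraries. The 24 measured cardiac transcription factors were not called (camera adjusted p = 0.939), with Heyl at a log2 fold change of 0.41. Neither were the 24 sarcomere and Z-disc genes (0.939), in which Myom2 had a log2 fold change of -0.46 and Ttn 0.23, the 20 calcium handling genes (0.939), with Itpr2 at 0.32 and Cacna1c at 0.15, nor the 17 genes of the fetal and hypertrophy programme (0.939), with Tnni1 at -1.27 and the skeletal actin gene Acta1 at 1.12.

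Genes of fatty acid oxidation and of oxidative phosphorylation were called by camera as lower sets. Of 33 fatty acid oxidation genes, 28 were lower in knockout, with a median log2 fold change of -0.13 (camera adjusted p = 1.29e-04; adjusted p = 0.754 with an estimated correlation). Decr1 and Acaa2, mitochondrial enzymes of beta-oxidation, had log2 fold changes of -0.35 and -0.33 (edgeR adjusted p = 0.606 and 0.626). Of 57 nuclear-encoded oxidative phosphorylation genes, 44 were lower, with a median of -0.07 (camera adjusted p = 0.00493; adjusted p = 0.962 with an estimated correlation), Cox8b and Uqcrb having the smallest p. The groups overlapped in the score of the oxidative phosphorylation list, at 0.067 in knockout replicate 1 against -0.069 and 0.060 in wild-type replicates 2 and 3. The fatty acid oxidation call was lost without knockout replicate 3 (camera adjusted p = 0.0791), and that of oxidative phosphorylation without wild-type replicate 1 (0.443), wild-type replicate 3 (0.0528), knockout replicate 2 (0.0551) or knockout replicate 3 (0.496). The 23 genes of glycolysis and glucose uptake were not called (camera adjusted p = 0.939), with Eno3 at a log2 fold change of -0.25 and Aldoa at 0.12.

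Genes of the extracellular matrix were higher as a set. In this list 27 of 34 members were higher in knockout, with a median log2 fold change of 0.21 (camera adjusted p = 1.26e-04; adjusted p = 0.754 with an estimated correlation). The proteoglycan gene Bgn and the collagen crosslinking enzyme gene Loxl2 had log2 fold changes of 0.42 and 0.56 (edgeR adjusted p = 0.510 and 0.728). The list's score was lowest in wild-type replicate 1 (-0.37, as mean log2 CPM against the mean of all libraries) and in knockout replicate 2 (-0.14), so the groups overlapped, and the call was lost without knockout replicate 3 (camera adjusted p = 0.0593). Endothelial markers were higher for 11 of 15 members, with Cldn5 at a log2 fold change of 0.46 and Eng at 0.23 (camera adjusted p = 0.0164; adjusted p = 0.754 with an estimated correlation), and this call was lost without wild-type replicate 1 (0.443) or knockout replicate 3 (0.0802). Fibroblast markers, with Col1a1 at 0.37 and Mfap5 at 0.26, and mural cell markers, with Notch3 at 0.33 and Rgs5 at 0.20, were not called (camera adjusted p = 0.0903 and 0.133). Both were called as higher without wild-type replicate 2 (0.00445 and 0.0371), and the fibroblast markers also without knockout replicate 1 (0.00537).

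Genes of the heat shock and unfolded protein response were higher for 21 of 24 members, with Hspb7 at a log2 fold change of 0.28 and Asns at 0.69 (camera adjusted p = 2.25e-04; adjusted p = 0.774 with an estimated correlation). The list's score was 1.08 in knockout replicate 1, -0.18 and -0.44 in the other knockout libraries and -0.37 to -0.03 in wild type, and without knockout replicate 1 the direction turned to lower (camera adjusted p = 0.113). Immediate early genes stood highest in the same library, at 1.65, and were not called with all libraries (camera adjusted p = 0.174), with Ier3 at a log2 fold change of 0.32 and Nr4a2 at 1.54. Without knockout replicate 1 the immediate early genes were called toward lower levels (camera adjusted p = 1.22e-13), and toward higher levels without knockout replicate 2 (7.13e-08), knockout replicate 3 (0.0129) or wild-type replicate 3 (0.0456) and with Y-linked reads as a term (5.07e-08). Cell cycle genes were higher for 22 of 25 members, with Tyms at a log2 fold change of 0.76 and Cenpe at 0.98 (camera adjusted p = 5.81e-04; adjusted p = 0.774 with an estimated correlation). Their score was 0.64 in knockout replicate 3, without which the call was lost (camera adjusted p = 0.415), and lower in the 3 libraries with Y-linked reads than in the others; with that presence as a term it was lost as well (0.146). Oxidative stress genes, with Nqo1 and Cat (0.17), circadian clock genes, with Cry2 at 0.22, and lysosome and autophagy genes, with Ulk1 at 0.20 and Ctsl at 0.19, were not called (camera adjusted p = 0.127, 0.383 and 0.0639). Targets of p53, with Bnip3 at 0.25 and Trp53inp1 at -0.24, were not called either (camera adjusted p = 0.939).

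Atrial cardiomyocyte markers were lower for 12 of 13 members, with a median log2 fold change of -0.96 (camera adjusted p = 9.77e-06; adjusted p = 0.754 with an estimated correlation). Kcnj3, a subunit of the acetylcholine-gated potassium channel, had a log2 fold change of -0.26 (edgeR adjusted p = 0.649). The list stood higher in each of the 3 libraries with Y-linked reads, of which wild type holds 2 and knockout 1: its score was 1.34, 0.43 and 0.24 in these and -0.86 to -0.31 in the others. The atrial call held with Y-linked reads as a term (camera adjusted p = 1.21e-05) and without any 1 library. The ventricular markers were not called (camera adjusted p = 0.726), with Kcnd2 lower and Fhl2 at a log2 fold change of 0.18. Erythroid markers were lower for 11 of 12 members, with Hbb-bs at a log2 fold change of -0.50 (camera adjusted p = 2.25e-04; adjusted p = 0.754 with an estimated correlation), and also stood higher in the libraries with Y-linked reads. The erythroid call held with that presence as a term (camera adjusted p = 0.0239) and without any 1 library. Adipocyte markers were lower for 12 of 13 members, with Adipoq at a log2 fold change of -2.13 and Cox8b at -0.24 (camera adjusted p = 0.00493; adjusted p = 0.774 with an estimated correlation). That call rested on wild-type replicate 2, with a score of 1.21: without it the direction turned (camera adjusted p = 0.994), and it was also lost without knockout replicate 1 (0.104) and with Y-linked reads as a term (0.0670).

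**Figure D3:**
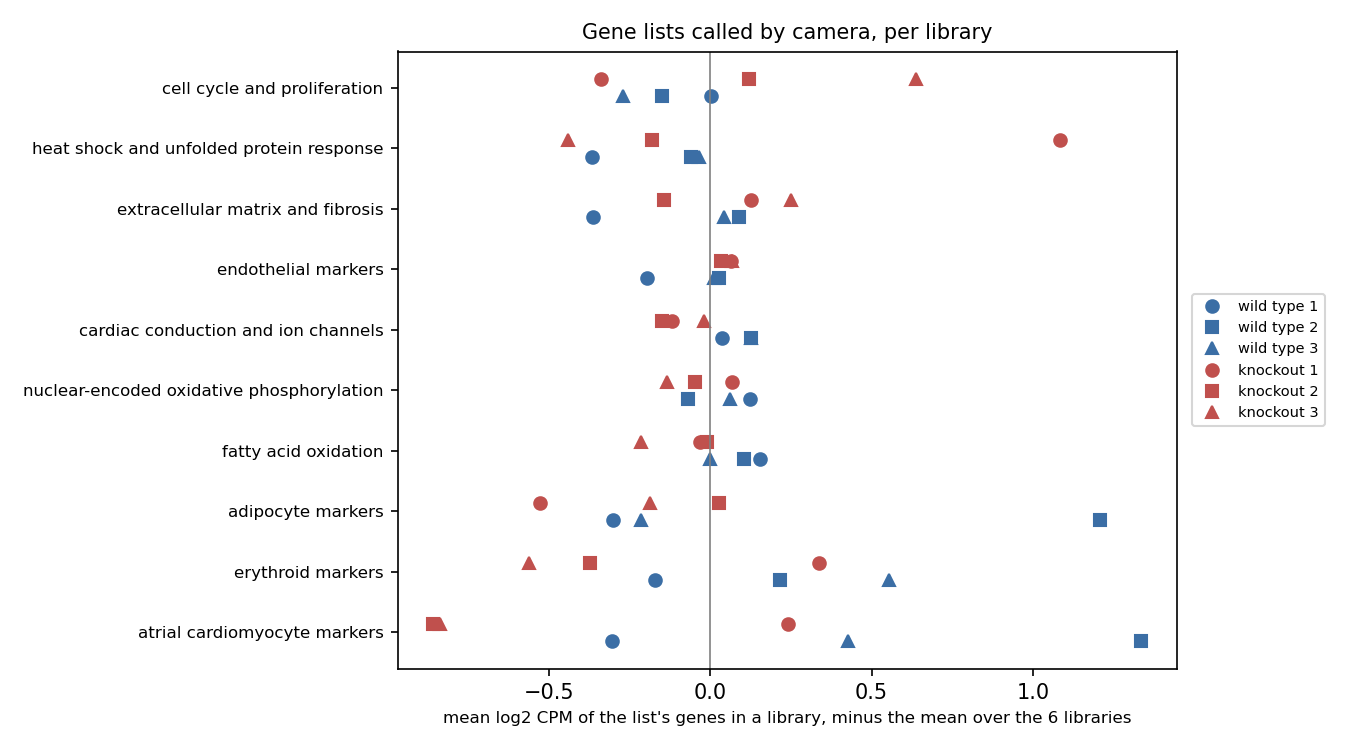
Score of each of the 10 lists that camera called, as the mean log2 CPM of the list's genes in a library minus the mean over the 6 libraries, with a marker for each library. The conduction scores lie between -0.15 and 0.13, while the atrial score of wild-type replicate 2 (1.34), the adipocyte score of the same library (1.21) and the heat shock score of knockout replicate 1 (1.08) stand apart.

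The remaining lists were not called. In the list of urea transport, urea cycle and aquaporin genes, the water channel gene Aqp4 had a log2 fold change of -0.53 (edgeR adjusted p = 0.501) and the endothelial nitric oxide synthase gene Nos3 one of 0.33 (edgeR adjusted p = 0.626), and camera gave an adjusted p of 0.939 for its 17 measured members. The inflammatory list, with Tnf at 1.29 and Nfkbia at -0.28, and the interferon list, with Ifi27 at -0.29, both had a camera adjusted p of 0.939. Macrophage markers had 0.939, with Cd14 at 0.58 and Cd163 at -3.05 (873, 1654 and 1424 reads in wild type, 10, 6 and 505 in knockout). Lymphocyte markers, with Cd3g at 1.59 and Ltb at 1.12, had 0.133. Schwann and neuronal markers, with Tubb3 and Dbh (-0.64), had 0.939, epicardial markers, with Tbx18 at -0.52 and Lrrn4 at -0.60, had 0.0808, and skeletal muscle markers, with Acta1 and Atp2a1 (-1.68), had 0.943. The 4 measured sex-linked genes were not tested as a list, and Uty and Eif2s3y had log2 fold changes of -1.02 and -0.85 that follow the number of libraries with Y-linked reads. Some of these lists were called when a library was left out. Called as lower were the fetal programme without wild-type replicate 1 (camera adjusted p = 0.0353) or knockout replicate 1 (0.00532), the epicardial markers without the same libraries (0.00121 and 5.95e-04), and the interferon list (0.0456) and the macrophage markers (0.00130) without knockout replicate 2. Lymphocyte markers were called as higher without wild-type replicate 2 (0.0205) or knockout replicate 1 (0.0351), autophagy genes without wild-type replicate 3 (0.0145) or knockout replicate 3 (0.0188), and oxidative stress genes without knockout replicate 3 (0.0309). The inflammatory list was called as lower without wild-type replicate 1 (0.0293) and as higher with Y-linked reads as a term (0.00128), a term with which the oxidative stress (0.0173) and autophagy (0.00668) lists were called as higher too. The median, mean and test of a list differed in sign for 11 lists, 0 of them called.

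Genes beside Slc14a1 were examined because a targeted locus can keep flanking sequence of the strain in which it was made. Within 20 Mb of Slc14a1, edgeR called 0 of 123 genes and 0 of the 13669 others, which leaves nothing to compare, and 10 of 123 against 207 of 13669 had an unadjusted p under 0.01 (Fisher's exact test, two-sided, p = 2.41e-05, odds ratio 5.75), a threshold added after the data were seen. DESeq2 called 5 of the 123, which were Rbfa, Pqlc1, Iigp1, Hsbp1l1 and Rttn, against 72 of 13648 (Fisher's exact p = 6.2e-04, odds ratio 7.99). Hsbp1l1 was named after its values were seen. Of the 5, only Rttn was higher in knockout. The Fisher tests take the genes as independent, which neighbouring genes may not be.

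In the lncRNA table, single transcripts were present in all libraries of a genotype and nearly absent from the other, and none passed the threshold with edgeR. Autosomal transcripts with a rounded count of 0 throughout 1 group and at least 10 in every library of the other numbered 17. Other splits of the 6 libraries, 3 against 3, gave 6 to 12 of them, so the pattern also arose across genotypes. Summed over overlapping transcripts of 1 strand, they numbered 9, and 9 in the highest other split. NONMMUT055379.2, on chromosome 5 from 148990055 to 148995214 on the minus strand, 19747 bp from Gm15411, had 155, 265 and 203 estimated reads in the wild-type replicates and 0, 0 and 0.443 in knockout (edgeR adjusted p = 0.0771). NONMMUT139823.1, on chromosome 10 from 130413216 to 130413620 and 4641 bp from the vomeronasal receptor gene Vmn2r85, had 113, 220 and 180 reads in wild type and 0 in each knockout library (edgeR adjusted p = 0.0771). Higher in knockout, NONMMUT002633.2 on chromosome 1, from 133138052 to 133139780, had 544, 107 and 435 reads against at most 0.749 in wild type (edgeR adjusted p = 0.176). edgeR called 0 of 10169 transcripts, with 467 at an unadjusted p under 0.05 where 508.5 were expected by chance, and DESeq2 called 129 (73 higher, 56 lower). On counts summed over overlapping transcripts of 1 strand edgeR called 0 of 8689, with 416 at an unadjusted p under 0.05, and DESeq2 43 (27 higher, 16 lower). In simulated lncRNA counts edgeR found 4.08% of transcripts changed 8-fold, so a count of 0 says little at this depth and spread; without wild-type replicate 1 there was 1 call, NONMMUT020724.2.

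Of the other named lncRNAs, NONMMUT106410.1 near Fam160b1, NONMMUT017156.2, NONMMUT100624.1 near Gpr31b and NONMMUT013222.2 were higher in knockout. NONMMUT015228.2, NONMMUT150401.1 and NONMMUT098754.1 were lower. Of the 10 named lncRNAs, 0 passed with edgeR and all 10 with DESeq2, where the largest adjusted p was 1.63e-04 for NONMMUT013222.2. They too were picked by edgeR p from the same counts. NONMMUT002633.2, NONMMUT017156.2, NONMMUT013222.2 and NONMMUT015228.2 lie in exons of Ppp1r15b, Smim13, Kif3c and Gtf2a1 on the same strand, so their reads cannot be told from those of the mRNA. The mRNAs of these genes had log2 fold changes of 0.09 for Ppp1r15b, 0.06 for Smim13, 0.02 for Kif3c and 0.07 for Gtf2a1 (edgeR adjusted p = 0.897, 0.918, 0.988 and 0.886). For transcripts that overlap others, the sum over the overlapping transcripts of 1 strand differed less. NONMMUT055379.2 belongs to a group of 35 whose summed counts had a log2 fold change of -0.27, and NONMMUT100624.1 to a group of 10 with 0.30. For NONMMUT150401.1 the sum over 6 transcripts gave -0.48. That of NONMMUT106410.1, over 6 as well, stayed at 1.69 (edgeR adjusted p = 0.986). The pair NONMMUT020724.2 and NONMMUT020725.2 gave 602183 to 739136 reads in every library together, while NONMMUT020724.2 alone had 215 and 342 in wild-type replicates 2 and 3 and at least 203001 in the other libraries.

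Circular RNAs differed little between genotypes relative to their spread. circRNA_0024, on chromosome 1 from 13221307 to 13286025, had 8, 11 and 6 junction reads in the wild-type replicates and 24, 17 and 13 in knockout, a log2 fold change of 1.21 with a standard error of 0.38 (edgeR adjusted p = 0.761). circRNA_2053, on chromosome 15 from 88811297 to 88812159, had 11, 19 and 17 against 6, 6 and 6, a log2 fold change of -1.25 with a standard error of 0.41 (edgeR adjusted p = 0.761). circRNA_5525, on chromosome 9 from 63616686 to 63619231, had 21, 14 and 11 against 3, 7 and 0. The other named ones were circRNA_0660, circRNA_3056, circRNA_4396 and circRNA_1153, higher in knockout, and circRNA_2787, circRNA_4270 and circRNA_0724, lower, none of which passed with edgeR or DESeq2. edgeR called 0 of 282 circRNAs, with 14 at an unadjusted p under 0.05 where 14.1 were expected by chance, and DESeq2 called 0. The tested circRNAs had a median of 17 junction reads per library and held 54.5% of all junction reads, and simulated 2-fold changes were found in 28.6% of cases. Leaving out wild-type replicate 1 gave 1 call, circRNA_3187, and leaving out knockout replicate 2 gave 1, circRNA_0401.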

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

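The term for Y-linked reads, the sums over overlapping lncRNAs and the unadjusted threshold beside Slc14a1 were chosen after the data were seen; the other alternatives were planned. The 0 mRNA calls became 77 with DESeq2, 2 with no low-count filter (Cngb3 and Myo3a), 2 with the presence of Y-linked reads as a term (Myot and Scn4b), 199 with DESeq2 and that term, and 145 at an unadjusted p under 0.05 with at least a 2-fold change; leaving out a library gave 0 to 1. The 0 lncRNA calls became 129 with DESeq2, 43 with DESeq2 on sums over overlapping transcripts (0 with edgeR on them), 590 with no filter, 4 and 17 with limma on FPKM at a pseudocount of 1 and 0.1, and 371 at the unadjusted threshold, with 0 to 1 when a library was left out. The 0 circRNA calls became 14 with no filter and 6 at the unadjusted threshold, with 0 to 1 when a library was left out. DESeq2 tested more features and made false calls in simulated unchanged mRNA and lncRNA counts. Whether either accounts for its extra calls was not tested, nor was the cause of the changes under the other settings.

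With the replicate number as a replicate block there were 0 mRNA, 0 lncRNA and 0 circRNA calls and 10 list calls. Libraries of the same number had deviations correlated at -0.20, -0.11 and -0.06, so the values show no pairing by number. The labels do not say whether the numbers pair the libraries, and these correlations cannot exclude it. The block changed no other call, and turned the log2 fold change of the Gata5 level to -0.21; limma at a pseudocount of 0.1 gave -0.024 for it. Leaving out a library moved the Gata5 level between -0.94 and 0.45 and the Slc14a1 level between -0.26 and 0.44, and neither gene passed the threshold. It moved the NONMMUT140591.1 level, a log2 ratio of 0.54 over all libraries, between -3.20 and 1.60, the lowest without knockout replicate 1. These ratios of NONMMUT140591.1 were not tested. With Y-linked reads as a term the named gene Uty turned to 0.025 and the named gene Eif2s3y to 0.16, and to 0.026 and 0.17 with DESeq2, as that term removes the difference it names. The 10 list calls became 0 with an estimated correlation and 0 with fry, 12 with Y-linked reads as a term, 8 of the 10 among them, and 8 to 12 when a library was left out, with only 5 to 9 of the 10 among them (5 without knockout replicate 3); the adjusted p of the heat shock list ran from 3.01e-11 to 0.113 and that of the adipocyte list from 2.61e-04 to 0.994, the highest with the direction turned. Calls within 20 Mb of Slc14a1 went from 0 to 5 with DESeq2 and to 10 at an unadjusted p under 0.01. Library totals alone moved the median log2 fold change of lncRNAs by 0.24, limma at a pseudocount of 0.1 by 0.11, and library sizes of the mRNA table that of circRNAs by -0.19. The planned circRNA comparison at 20 or more junction reads was not run, as no host genes were named. Depth limits the values of Slc14a1, NONMMUT140591.1 and circRNAs with few reads.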

Other observations

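The comparison of splits for the mRNA calls, the set size and distance of the neighbour count, the test without genes beside Slc14a1, both tests of exchanged labels and the comparison of the atrial list by Y-linked reads were chosen after the results they bear on had been seen. Beyond the markers named in the report, several genes stood apart in single libraries. Bmp10, a growth factor of the atria, reached 59.8 CPM in wild-type replicate 2 and 0.0216 to 1.75 CPM in the other 5 libraries. The heat shock gene Hspa1b stood at 770 CPM and the immediate early gene Fos at 78.2 CPM in knockout replicate 1, against 6.00 to 26.8 CPM and 1.95 to 18.6 CPM elsewhere. Mybphl, a myosin-binding protein gene with high levels in atria, ran from 34.9 to 81.4 CPM in the 3 libraries with Y-linked reads and from 5.80 to 8.88 CPM in the others, and the complement gene C7 from 39.3 to 41.6 against 2.75 to 6.29 CPM. Gata4 and Gata6, related to Gata5, ran from 80.1 to 94.3 and from 53.6 to 75.7 CPM over the 6 libraries.

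The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05 for any count. The labelled split gave 0 edgeR calls in the mRNA table and the highest of the other splits 26; with DESeq2 the labelled split gave 77 and the highest other 252, 2 of the 10 splits giving as many. Both of those highest counts came from the split that follows the Y-linked reads. Y-linked genes were counted with the rest, so part of each count was fixed by how that split was defined. The 252 are far more than the 4 genes that define it, which points to a structure of the samples other than genotype. In the lncRNA table the labelled split gave 0 edgeR calls and the highest other 1, and 129 DESeq2 calls against 87, in 1 of 10. For circRNAs the labelled split gave 0 and the highest other 1, and for the lists called by camera 10 against 14, with 9 of 10 splits calling as many.

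The autosomal genes that ranked highest by genotype tended to lie beside each other. Of the 50 with the smallest edgeR p, 17 had another of the 50 within 2 Mb, against a median of 6 and an upper bound of 14 for the central 95% of 10000 random sets (share of random sets as large, 0.0039), and 8 of the 17 lay on chromosome 17 and 5 on chromosome 18. With genes within 20 Mb of Slc14a1 left out, the count was 18, above the same bound. This argues against the hypothesis that sequence kept beside the targeted gene alone gave the closeness. The bound takes no account of neighbouring genes that vary together, so the count does not tell whether kept sequence had a part. Kept sequence of another strain at several loci may be a candidate explanation and was not tested, as no variants were read. Reads shared between adjacent genes stay open, since counting only neighbours over 100 kb apart gave 13, at the bound of 13 for such sets (share 0.037), and so does the uneven presence of Y-linked reads, since ranking with it as a term gave 12, under the bound of 14 (share 0.0933). Another split of the libraries gave 21 neighbours and 3 of the 10 splits gave at least 17, so genes that vary together for other reasons also lie close together.

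The 3 libraries with Y-linked reads held more atrial transcripts, the 13 measured atrial markers differing by a median of 1.14 on the log2 scale, 7 of them higher in each of the 3 libraries than in any other. An exchange of the labels of knockout replicate 1 and wild-type replicate 1 would make this the genotype split. The genes within 20 Mb of Slc14a1 argue against such an exchange. Of these, 10 had an edgeR p under 0.01 in the labelled split, 0 in the exchanged split and at most 4 in any other. The threshold was added after the data were seen, and neighbouring genes may vary together. The reading also assumes that genes beside a targeted locus differ by genotype, so it does not settle the exchange. An earlier test did not decide it: autosomal genes and summed overlapping lncRNAs with a rounded count of 0 throughout 1 group and at least 10 in every library of the other numbered 10 in the labelled split, 4 in the exchanged split and at most 9 in any other, within 2 SD of counting error. Sex of the animals and the share of atrial tissue taken cannot be told apart, because the same 3 libraries carry both marks, and either may account for the median of 1.14; of the 13 markers, 6 also stand in other lists.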
